A study of Mus musculus with 13 samples.

How the data were processed

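Bulk RNA sequencing was carried out on interfollicular keratinocytes, the epidermal cells between hair follicles, which were sorted by FACS from the skin of C57/BL6 mice. Per the labels' protocols, total RNA was purified with a micro-column kit, libraries were made by the Smart-seq2 method, which copies full-length cDNA and does not mark strand or carry molecular identifiers, and single-end reads of 100 bases came from a NovaSeq instrument. The deposited values were raw read counts per Ensembl gene, whole numbers that the authors had not normalized, with 1 column per sample. Per the submitters' processing notes, STAR, featureCounts of the Subread package and genome build GRCm38 were used. Their versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of near-identical gene copies and of overlapping or antisense genes are therefore uncertain.

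The labels placed 13 libraries in 4 groups. Mice with floxed Il12rb2 alleles and no Cre (floxed control) gave 3 untreated libraries and 3 libraries after Aldara, a cream with 5% imiquimod applied to the skin for 1 day. Mice that also carried K14Cre, which acts in keratinocytes (Il12rb2-deleted), gave 4 untreated and 3 Aldara libraries. A vehicle-treated group and a Cre group without floxed alleles were not analysed here. The labels number the replicates but do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. Total counts per library ranged from 5830034 to 22232478.

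The count table held 25746 genes, of which 1394 had no count in any library. Symbols came from the deposited count table. Coordinates and exonic lengths came from the GENCODE mouse release M21 annotation of GRCm38, which held 25635 of the gene identifiers. Of the symbols, 35 belonged to more than 1 identifier, 15 of them among tested genes. Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 16051. TMM factors, a quasi-likelihood negative binomial fit with 1 coefficient per group over all 13 libraries, and edgeR's quasi-likelihood F test gave 5 contrasts: Aldara against untreated in each genotype, Il12rb2-deleted against floxed control in each treatment, and the interaction, which is the difference between the Aldara effects. The common dispersion was 0.424. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, a gene was called at an adjusted p under 0.05, and standard errors (SE) were the log2 fold change divided by the square root of F. CPM values are the depth-scaled counts of edgeR, adjusted by the TMM factors, and principal components used log2 CPM with a prior count of 2.

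Before the data were examined, 28 gene lists were written down, covering interferon, type 3, cytokine, NF-kB and interleukin-12 genes, keratinocyte layers, wound, matrix, cell cycle, lipid, stress and clock genes, cell dissociation and mitochondrial genes, and markers of other cells the sort could hold. Of their 584 symbols, 582 were found, 5 of these through synonyms. The list called antigen presentation for short also holds interferon-gamma targets such as Cxcl9, Cxcl10 and Irf1. The sex-linked list had no tested member, and the other 27 were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 27. The number of members called when adjusted over the list alone was also recorded. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance one way, were alternatives. A list median was taken over the fitted log2 fold changes of its tested members. A range beside a list median gives its lowest and highest value with each of the 13 libraries left out in turn.

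The genes named were chosen by a rule written before the data were examined. In each contrast it takes the 12 called genes with the largest increase and the 12 with the largest decrease among genes with an average log2 CPM of at least 3 and no overlap between the groups' CPM values, leaving out predicted genes and clone names. Where fewer than 5 genes were called, it takes the 5 with the smallest p, as values that did not pass. Il12rb2, Il12rb1, Krt14 and Krt5 are named in every contrast, and from each list up to 4 members with the smallest p. A gene named in 1 contrast is at times given in another, and any other gene named, such as Gm10800, was chosen after its values were seen.

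The steps were tested on simulated counts with 100 genes changed at each of 2 fold sizes, drawn from the means and library sizes of these libraries. The changed genes were picked among those with an average log2 CPM of at least 3, so recovery was not measured for lower genes. Each gene was drawn independently, so shifts of many genes together in 1 library were not simulated. Recovery also depends on the number of genes changed, because the adjustment is stricter when few genes are called. It may be too high for contrasts with few calls and too low for those with many. Alternatives fixed in advance were RLE size factors, DESeq2, limma voom with sample quality weights, no filter on low counts, a minimum count of 50, the replicate number as a block, 1 surrogate variable from sva, fits of only the groups compared, and each library left out in turn. A covariate for sex was not run, because no library held more than 2 counts of Y-linked genes. Alternatives added after seeing the data were a covariate for the share of counts in the gene Gm10800, a batch term for the libraries with under 0.01% of counts in it, and the removal of the 3 libraries with over 5%. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Exact binomial intervals of shares at a 95% level, and floors at 3 counts for a count of 0, cover counting error only. Results for some genes are not reported here.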

Results

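The libraries measured transcripts of sorted interfollicular keratinocytes from mice with floxed Il12rb2 alleles, with or without K14Cre, before or after 1 day of topical Aldara. Imiquimod, its active compound, is an agonist of Toll-like receptor 7 and is used to produce psoriasis-like skin inflammation. The title of the series places the question in how interleukin-12 acts on type 3 immunity through keratinocytes. Depth was 12274346, 10226953 and 22232478 counts in floxed control untreated replicates 1 to 3, and 12700506, 5830034, 12529127 and 16511356 in Il12rb2-deleted untreated replicates 1 to 4. It was 15267712, 9256465 and 17977933 counts in floxed control Aldara replicates 1 to 3, and 9138243, 13476587 and 14089450 in Il12rb2-deleted Aldara replicates 1 to 3. The first principal component (27.3% of the variance) separated all Aldara libraries from all untreated ones. Il12rb2-deleted Aldara replicate 1 lay furthest out on it, at 159.5 against 38.3 to 63.0 in the other Aldara libraries. Its median Spearman correlation with the other libraries, 0.847, was also the lowest. The second component (20.2%) spread the untreated libraries, and along it lay the share of counts in Gm10800, a predicted gene. That share was 14.17% (95% exact binomial interval 14.14 to 14.19) in floxed control untreated replicate 2, and 5.21% (5.20 to 5.22) and 10.35% (10.32 to 10.37) in Il12rb2-deleted untreated replicates 1 and 2. It was 0.0065% (0.00617 to 0.00685) in floxed control untreated replicate 3, and 0.000543% (0.000422 to 0.000688) and 0.00127% (0.0011 to 0.00145) in Il12rb2-deleted untreated replicates 3 and 4.

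Il12rb2, which encodes the signalling subunit of the interleukin-12 receptor and is the floxed gene, lies on chromosome 6 at 67291318 to 67376188 on the minus strand (ENSMUSG00000018341, GRCm38). It was read at 17.1, 78.8 and 52.7 CPM in floxed control untreated replicates 1 to 3, and at 22.7, 8.52, 25.6 and 19.0 CPM in Il12rb2-deleted untreated replicates 1 to 4. After Aldara it stood at 1.98, 8.14 and 2.68 CPM in the floxed control libraries. In the Il12rb2-deleted Aldara libraries replicate 1 held 0 counts, which allows up to 0.307 CPM, and replicates 2 and 3 held 15 and 24 counts (1.07 and 1.64 CPM). The deletion difference was -1.38 in log2 (SE 0.69) untreated and -2.14 (SE 0.83) after Aldara, with edgeR adjusted p of 1 and 0.982, so it did not pass over all genes. Untreated it was -0.88 without floxed control replicate 2. After Aldara it was -1.30 without floxed control replicate 2, and it ran to -2.84 without Il12rb2-deleted replicate 3. All Il12rb2-deleted Aldara values lay below all floxed control Aldara values, at low counts, while the untreated values of the genotypes overlapped. The transcript was thus still counted in untreated libraries of the Cre genotype. The labels do not say which exons are floxed, and a gene-level count includes the exons outside them, so the count checks the genotype labels only in part. Aldara was accompanied by a fall in both genotypes, by 3.56 on the log2 scale (SE 0.83, adjusted p = 0.0192) in floxed control and by 4.33 (SE 0.86, adjusted p = 0.00391) in Il12rb2-deleted cells. The floxed control call was lost without untreated replicate 2 (adjusted p = 0.106) or 3 (0.0646), or Aldara replicate 1 (0.0833) or 3 (0.0539). Il12rb1, the other receptor subunit, was near the floor in untreated libraries, with 0 to 15 counts, and held 0, 15 and 121 counts in floxed control and 117, 48 and 52 counts in Il12rb2-deleted Aldara libraries. Neither Aldara difference of Il12rb1 passed (adjusted p = 0.217 and 0.138).

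**Figure D1:**
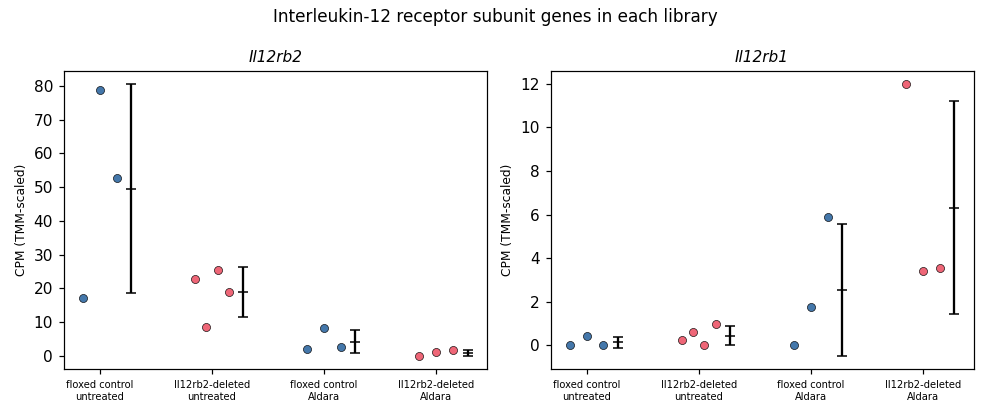
Il12rb2 (left) and Il12rb1 (right) in CPM, 1 point per library in the 4 groups, with the group mean and SD as a bar beside the points. Il12rb2 lies between 8.52 and 78.8 CPM in the 7 untreated libraries and at 8.14 CPM or lower in the 6 Aldara libraries.

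In floxed control keratinocytes, 1 day of Aldara was accompanied by lower transcripts of suprabasal and basal keratinocyte structure and by higher transcripts of sebaceous cell markers and of genes that interleukin-17 and interleukin-22 induce. As lists these passed camera and none passed with an estimated correlation (adjusted p of 0.285 to 0.364). Fry called 8 of the 27 lists tested in this contrast. Krt10, the keratin of cells that have left the basal layer (chromosome 11, 99385254 to 99389364, minus strand), went from 1659.5 ± 609.5 CPM (SD, n = 3) to 90.2 ± 23.9 (SD, n = 3), a log2 change of -4.20 (SE 0.60, edgeR adjusted p = 0.00292). Its partner Krt1 fell by 3.24, the desmosomal cadherin Dsg1a by 3.63 and Krtdap by 2.08 on the log2 scale. Of 23 tested suprabasal and cornified envelope genes, these 4 fell and none rose (5 fell when adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.364 with an estimated correlation). Of 22 basal and basement membrane adhesion genes, 8 fell and none rose (10 fell adjusted over the list alone; camera adjusted p = 1.42e-07, and adjusted p = 0.285 with an estimated correlation). Among them were Krt15 (-2.17, SE 0.47), Col17a1 of the hemidesmosome (-1.71, SE 0.35) and the anchoring fibril collagen Col7a1 (-2.01, SE 0.32).

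Sebaceous cell markers, which are genes of lipid synthesis and storage, were higher after Aldara in the floxed control cells. Of 15 tested, 9 rose and none fell (13 adjusted over the list alone), with a median log2 change of 1.98 and a camera adjusted p of 1.84e-13 (adjusted p = 0.285 with an estimated correlation). Far2, a fatty alcohol-forming enzyme on chromosome 6 (148047259 to 148182758, plus strand), went from 102 ± 47.2 CPM (SD, n = 3) to 859 ± 161 (SD, n = 3), a log2 change of 3.07 (SE 0.43). Elovl3 rose by 3.35 and the lipid droplet protein Plin2 by 2.68. Cholesterol biosynthesis genes followed, with 7 of 19 higher, among them Mvd (2.45) and Sqle (1.47), and 13 adjusted over the list alone (camera adjusted p = 4.63e-07, and adjusted p = 0.285 with an estimated correlation). In the NRF2 oxidative stress list 4 of 18 rose, among them Gclm (1.75) and Txnrd1 (1.28), and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.000423, and adjusted p = 0.079 with an estimated correlation). In the unfolded protein response list 3 of 18 rose, among them the chaperone Hspa5 (1.03), and Atf3 fell (9 up and 1 down adjusted over the list alone; camera adjusted p = 0.0048, and adjusted p = 0.331 with an estimated correlation). That list was no longer called without floxed control untreated replicate 2 (adjusted p = 0.0639).

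The type 3 list holds keratinocyte genes that interleukin-17 and interleukin-22 induce. In floxed control cells 3 of its 19 tested members rose, and 5 adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.285 with an estimated correlation). These were Lcn2, an iron-scavenging antimicrobial protein (chromosome 2, 32384633 to 32388252, minus strand; 47.8 ± 71.7 to 858 ± 505 CPM, SD, n = 3 each; log2 change 4.17, SE 1.15, and 7.03 without untreated replicate 1, which held 130.5 CPM), S100a8 (4.20, SE 1.16) and the protease inhibitor Slpi (3.98, SE 1.14). Cell cycle genes went both ways: 10 of 30 rose and 2 fell (12 and 3 adjusted over the list alone). Among those that rose were Ccne1 (3.86), Rrm2 (2.49) and Mcm2 (1.99). The list's median was -0.03 (-0.10 to 0.23 with a library left out) while its mean was 0.48 and camera's direction was up (adjusted p = 0.0124, and 0.598 as an adjusted p with an estimated correlation), a call lost without floxed control untreated replicate 2 (adjusted p = 0.292). Of the list of immediate-early genes known from cell dissociation, 5 of 20 fell, among them Fos (-1.92) and Zfp36 (-1.94), and Hspa8 rose (8 down and 2 up adjusted over the list alone; camera adjusted p = 5.44e-05, and adjusted p = 0.364 with an estimated correlation). The clock list was lower, with Bhlhe40 (-1.70) the 1 call of 18 and the 1 adjusted over the list alone (camera adjusted p = 0.00816, and adjusted p = 0.285 with an estimated correlation).

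Markers of cells that a keratinocyte sort should exclude were also lower after Aldara in floxed control libraries. In the fibroblast list 4 of 18 fell, among them Lum (-2.95) and Col1a2 (-2.07), and adjusted over the list alone 9 fell and 1 rose, with a camera adjusted p of 5.22e-06 (adjusted p = 0.286 with an estimated correlation). In the list of endothelial and mural cells Rgs5 fell (-3.07), the 1 call of 15 and the 1 adjusted over the list alone, with a camera adjusted p of 0.0015 (adjusted p = 0.364 with an estimated correlation). No member was called among 17 Langerhans cell and macrophage markers, 20 hair follicle markers, 14 melanocyte and Merkel cell markers or 12 mitochondrial transcripts, and none of these lists passed camera. The same held for the 30 type I interferon genes, whose median was 0.35 (-0.09 to 1.89 with a library left out; camera adjusted p = 0.0501). That list passed without any 1 of 10 libraries, and without floxed control untreated replicate 1, which held Isg15 at 85.7 CPM against 3.94 and 3.20 CPM in replicates 2 and 3, its median was 1.89 (adjusted p = 3.6e-07). Of the remaining lists, which did not pass camera, 3 of 24 alarmin, cytokine and chemokine genes fell (Il1rn, Il34 and Cxcl14; 6 down and 1 up adjusted over the list alone; camera adjusted p = 0.0501). Of 18 NF-kB genes 2 rose and 2 fell (2 and 6 adjusted over the list alone), and 2 of 18 genes of interleukin-12 and -23 signalling fell (Il12rb2 and Socs3). Gjb2 and Krt6b rose among 20 wound genes, Ccn1 and Itga2 fell among 24 matrix genes, Gapdh and Pgk1 rose and Ndrg1 fell among 22 glycolysis genes, and Elovl4 rose among 22 barrier lipid genes. Cxcl10, Trbc2 and Il1r2 fell, each the 1 call among the lists of antigen presentation and interferon-gamma targets, T cells and neutrophils. Some of these lists passed with 1 library left out. The alarmin list passed without floxed control untreated replicate 2 (adjusted p = 0.0481) or Aldara replicate 3 (0.0129), or Il12rb2-deleted untreated replicate 1 (0.0433) or 4 (0.05) or Aldara replicate 1 (0.0352). The NF-kB list passed without floxed control untreated replicate 1 (adjusted p = 0.0292) or Aldara replicate 2 (0.0167) or 3 (0.0496), or Il12rb2-deleted Aldara replicate 1 (0.0368). Matrix genes passed without floxed control untreated replicate 1 (adjusted p = 0.0351) or Aldara replicate 3 (0.0473), wound genes without floxed control Aldara replicate 1 (0.0427) and glycolysis genes without floxed control untreated replicate 3 (0.0366).

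Outside the lists, the transcripts that fell furthest in floxed control cells included the potassium channel gene Kcnj16 (-6.32), the metallothionein Mt4 (-5.78), Skint10 (-5.74) and Skint9 (-4.80), relatives of the selecting gene for dendritic epidermal T cells, Wnt16 (-4.57), Guca2a (-4.53) and H60c (-4.12), a ligand of NKG2D. Those that rose furthest included the acyl-CoA thioesterase Acot5 (5.20), Fbp1 (4.24), St3gal5 (4.16), Pnpla5 (3.64), Rdh1 (3.60) and Pctp (3.51). In total edgeR called 1132 of 16051 genes, 666 higher and 466 lower, around a median change over all genes of -0.127 in log2. On simulated data for this comparison 5 of 100 genes changed 2-fold and 73 of 100 changed 4-fold were recovered. The count was 270 without the 3 libraries high in Gm10800, 215 and 288 without untreated replicate 2 or 3, and 422 and 618 without Aldara replicate 1 or 2. Of the 78 named genes called, 61 lost the call with some library left out (highest adjusted p = 0.211), among them Lcn2, S100a8, Slpi and Krt6b, while Krt10, Dsg1a, Far2, Rrm2, Ccne1, Mt4, Acot5 and Rdh1 did not. With limma voom the highest adjusted p among the 78 was 0.39, for Krt6b.

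**Figure D2:**
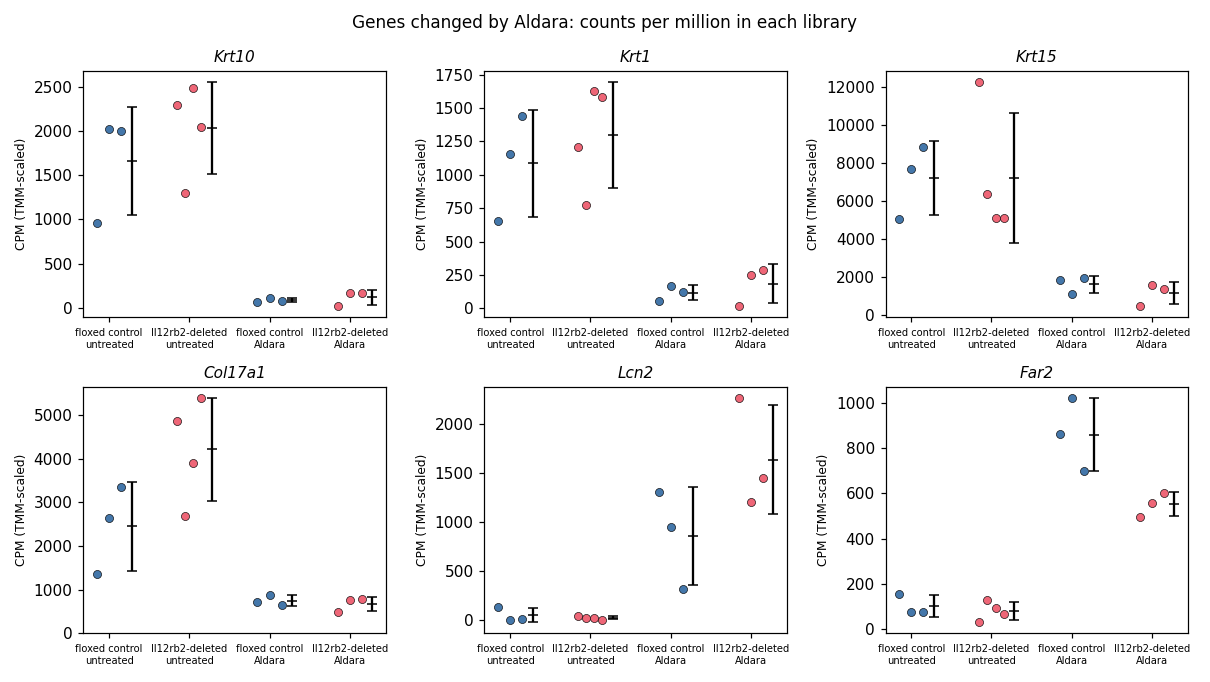
CPM of Krt10, Krt1, Krt15, Col17a1, Lcn2 and Far2, 1 point per library in the 4 groups, with the group mean and SD as a bar beside the points. Krt10 falls from a mean of 1659.5 to 90.2 CPM in floxed control and from 2030.3 to 119 CPM in Il12rb2-deleted cells, and Far2 rises from 102 to 859 and from 79.4 to 552 CPM.

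In Il12rb2-deleted keratinocytes, Aldara was accompanied by lower transcripts of suprabasal and basal keratinocyte structure and by higher transcripts of sebaceous cell markers and type 3 genes. As lists these passed camera and none passed with an estimated correlation (adjusted p of 0.0932 to 0.256). Fry called 13 of the 27 lists tested in this contrast. Krt10 went from 2030.3 ± 522 CPM (SD, n = 4) to 119 ± 83.3 (SD, n = 3), a log2 change of -4.10 (SE 0.58, edgeR adjusted p = 0.000729), and Dsg1a fell by 4.16. Of 22 basal and basement membrane adhesion genes 15 fell and none rose (17 fell adjusted over the list alone; camera adjusted p = 2.26e-13, and adjusted p = 0.0932 with an estimated correlation). They included Col17a1 (-2.62, SE 0.35), Col7a1 (-2.96, SE 0.33), Krt5 (-1.58, SE 0.31) and Krt14 (-1.49, SE 0.35), the keratin pair of the basal layer. Of 23 suprabasal genes 7 fell and 1 rose (8 down and 1 up adjusted over the list alone; camera adjusted p = 0.000265, and adjusted p = 0.256 with an estimated correlation). Of 15 sebaceous markers 11 rose and none fell (13 adjusted over the list alone; camera adjusted p = 1.22e-11, and adjusted p = 0.175 with an estimated correlation), with Elovl3 at 3.63, Fabp5 at 2.84, Plin2 at 2.82 and Far2 at 2.80. In the NRF2 list 9 of 18 rose and none fell, among them Gclm (2.17) and Me1 (1.64), and 10 rose adjusted over the list alone, with a camera adjusted p of 0.000665 (adjusted p = 0.0932 with an estimated correlation). Cholesterol genes went both ways, with Mvd (1.93) among 4 that rose and Sc5d among those that fell, and did not pass camera (adjusted p = 0.0593). They passed without Il12rb2-deleted untreated replicate 3 (adjusted p = 0.00161) or 4 (0.0161) or Aldara replicate 3 (0.0263).

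In the type 3 list 7 of 19 rose and 1 fell (9 up and 1 down adjusted over the list alone; camera adjusted p = 0.00154, and adjusted p = 0.0932 with an estimated correlation). The list's median of 1.61 was 0.0441 without Aldara replicate 1. Lcn2 went from 20.0 ± 15.6 CPM (SD, n = 4) to 1640.5 ± 558 (SD, n = 3), a log2 change of 6.36 (SE 1.13), Slpi rose by 6.60, S100a8 by 4.72 (7.28 without untreated replicate 4) and the neutrophil-attracting chemokine Cxcl1 by 1.66. Alarmin, cytokine and chemokine genes were lower as a list, with 10 of 24 down and 1 up (13 and 1 adjusted over the list alone; camera adjusted p = 0.000695, and adjusted p = 0.13 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, fell by 3.02, Il33 by 1.75 and Cxcl14 by 1.53. Among NF-kB genes 7 of 18 fell, including the decoy receptor Il1r2 (-4.25) and Icam1 (-2.32), and 2 rose (8 down and 2 up adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.252 with an estimated correlation). In the list of interleukin-12 and -23 signalling 5 of 18 fell, among them Il12rb2, Il18r1 (-2.21) and Socs3 (-2.07), as many as adjusted over the list alone, with a camera adjusted p of 0.0313 (adjusted p = 0.256 with an estimated correlation). The call was lost without untreated replicate 1 (adjusted p = 0.059) or Aldara replicate 3 (adjusted p = 0.0546). Immediate-early genes fell in 11 of 20, and none rose (14 down and 1 up adjusted over the list alone; camera adjusted p = 4.85e-06, and adjusted p = 0.256 with an estimated correlation). Matrix and migration genes fell in 8 of 24, with Thbs1 at -2.29 (9 adjusted over the list alone; camera adjusted p = 0.000855, and adjusted p = 0.256 with an estimated correlation). Clock genes fell in 3 of 18, with Bhlhe40 at -2.44 (5 adjusted over the list alone; camera adjusted p = 0.00517, and adjusted p = 0.117 with an estimated correlation).

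The type I interferon list had 29 of 30 members higher with a median of 1.16, yet none was called singly or adjusted over the list alone (camera adjusted p = 7.43e-05, and adjusted p = 0.629 with an estimated correlation). Without Il12rb2-deleted untreated replicate 2 its median was 2.92. Isg15 stood at 25.5 CPM in Il12rb2-deleted untreated replicate 2 and at 0.622 to 1.29 CPM in the other 3 untreated libraries. Among 25 antigen presentation and interferon-gamma target genes Cxcl9 (2.24), H2-Aa (1.69) and H2-Ab1 (1.91) rose and Irf1 fell by 1.84. Each lost the call with some library left out: Cxcl9 and H2-Ab1 with 9 of 13 (adjusted p up to 0.165 and 0.167), Irf1 with 7 (up to 0.09) and H2-Aa without Aldara replicate 3 (0.0852). The list did not pass camera (adjusted p = 0.0854) except without Il12rb2-deleted untreated replicate 2 (0.00186) or Aldara replicate 1 (0.00262). Fibroblast markers were again lower, with 10 of 18 down and 1 up (15 down and 1 up adjusted over the list alone; camera adjusted p = 1.22e-11, and adjusted p = 0.0932 with an estimated correlation). Col1a1 went from 368 ± 125 CPM (SD, n = 4) to 9.97 ± 8.86 (SD, n = 3), a log2 change of -5.19 (SE 1.04), and Lum fell by 5.66. The remaining lists did not pass camera. That of endothelial and mural cells (adjusted p = 0.0805) passed without Il12rb2-deleted untreated replicate 3 (0.0155) or 4 (0.0164) or Aldara replicate 1 (0.0145). Within them 6 of 30 cell cycle genes rose and 4 fell, 4 of 18 unfolded protein response genes rose and 3 fell, 1 of 22 glycolysis and hypoxia genes rose and 6 fell, and 2 of 22 barrier lipid genes rose and 3 fell. Gjb2 rose and Plaur and Il20rb fell among the wound genes, Cd34, Thy1 and Il1r2 fell as the 1 call each among hair follicle, T cell and neutrophil markers, and no mitochondrial, endothelial, Langerhans cell or melanocyte and Merkel cell gene was called.

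Outside the lists Ccdc80, a secreted matrix protein gene (chromosome 16, 45093402 to 45128077, plus strand), fell by 7.45, the glucose transporter family member Slc2a6 by 7.31, Guca2a by 7.03, Mt4 by 5.93, Kcnj16 by 5.68 (a change of -9.12 without Aldara replicate 3) and Skint9 by 5.10. Krt19 was at 126 ± 225 CPM (SD, n = 4) before and 0.136 ± 0.236 CPM (SD, n = 3) after Aldara, a log2 change of -10.08 with an SE of 2.58. The change was -6.96 without untreated replicate 1, and the call was lost without any 1 of the 3 Aldara replicates (adjusted p of 0.0537 to 0.0634) and with limma voom (0.374). Acot5 rose by 5.66, Pctp by 5.40 (11.92 without the 3 libraries high in Gm10800), St3gal5 by 5.35, Klk6 by 5.15 and Fbp1 by 4.49. In total 2489 of 16051 genes were called, 1254 higher and 1235 lower, and on simulated data for this comparison 10 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered. The count was 1466 without the 3 libraries high in Gm10800 and 1650 without untreated replicate 1. Of the 98 named genes called, 24 lost the call with some library left out (highest adjusted p = 0.167).

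The Aldara effects in the 2 genotypes share no library. Of the genes that passed in both, 557 rose in both, against 52.0 expected for independent lists, 385 fell in both, against 35.9, and 0 went opposite ways. Across 16051 genes, which are not independent replicates, Pearson's r between the log2 changes was 0.513 and Spearman's rho 0.594, with the same sign in 75.2%. The correlation moved with the genes taken in, from 0.248 with no filter on low counts to 0.725 at a minimum count of 50. A further 1547 genes passed in Il12rb2-deleted cells and not in floxed control cells, and 190 the other way, but the test of the difference itself, the interaction, called none of them.

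**Figure D3:**
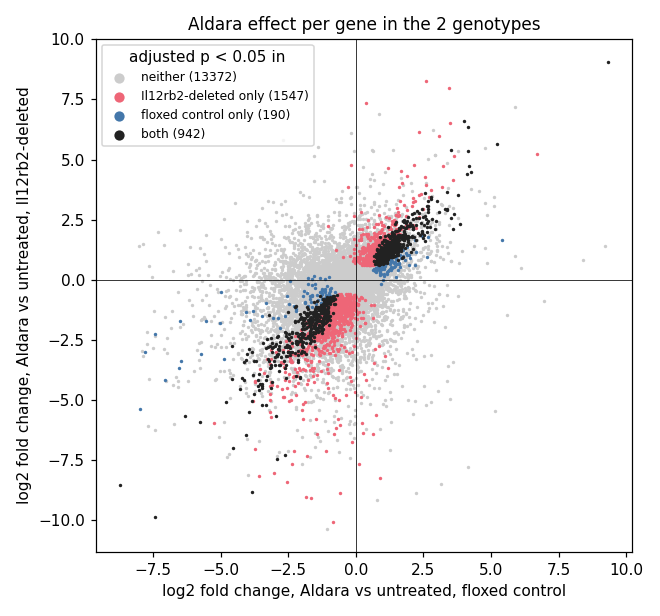
Log2 fold change of Aldara against untreated for each of 16051 genes in floxed control (x axis) and Il12rb2-deleted (y axis) keratinocytes, coloured by the genotypes in which edgeR called the gene. The genes called in both (dark points) lie in the quadrants where the sign is shared.

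In untreated skin, Il12rb2-deleted keratinocytes stood above floxed control cells in the lists of wound and stress genes and of alarmins and cytokines, by camera, but neither list passed with an estimated correlation (adjusted p = 0.147 and 0.113) or fry, and no single gene passed the test over all genes. Without Il12rb2-deleted replicate 4 the wound median was 0.74 in place of 1.78. Krt16, a keratin of wounded and hyperproliferative epidermis (chromosome 11, 100246091 to 100248902, minus strand), was at 139.9 ± 48.8 CPM (SD, n = 3) in floxed control and 1252 ± 850.5 (SD, n = 4) in Il12rb2-deleted libraries. Its log2 difference was 3.16 (SE 0.71, edgeR adjusted p = 0.874). The genes with the smallest p were Plet1 (1.56, SE 0.32), the natriuretic peptide gene Nppb (5.13, SE 1.05), Luc7l3 (-1.18, SE 0.25), Enpp2 (-1.73, SE 0.37) and Pctp (-3.93, SE 0.86), each at an adjusted p of 0.874. Krt14 and Krt5 differed by 0.83 and 0.64, both at an adjusted p of 1. EdgeR called 0 genes of 16051. An unadjusted p under 0.05 was reached by 599 genes, a smaller share of the 16051 than the 0.05 that chance alone gives on average. DESeq2 called 18 (16 higher, 2 lower, including Nppb, Krt16, Plet1, Tgfa and Tslp higher and Enpp2 and Luc7l3 lower). Limma voom called 0, and edgeR with no filter on low counts called 3 (Nppb, Krt16 and Pctp). Of the counts of all 13 libraries, Il12rb2-deleted untreated replicate 4 held 44.3% for Nppb, 39.2% for Krt16, 33.1% for Tslp and 20.4% for Plet1. For Tgfa, Enpp2, Luc7l3 and Pctp another library held the most. On simulated data for this comparison 8 of 100 genes changed 2-fold and 65 of 100 changed 4-fold were recovered, so 2-fold differences were mostly not detectable here. Recovery may be lower where few genes change.

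Gene lists differed in this comparison with no member called over all genes. The wound and stress list had 17 of 20 members higher in Il12rb2-deleted cells, with a median of 1.78 (camera adjusted p = 1.11e-07, and adjusted p = 0.147 with an estimated correlation), and 3 passed adjusted over the list alone. Krt6b (4.87, and 2.33 without Il12rb2-deleted replicate 4), Krt16 and the envelope precursor Sprr1b (3.12) had its smallest p. Of 24 alarmin, cytokine and chemokine genes 17 were higher (median 0.85, camera adjusted p = 1.63e-07, and adjusted p = 0.113 with an estimated correlation), 3 of them adjusted over the list alone. Tslp was at 10.2 ± 5.68 CPM (SD, n = 3) in floxed control and 122 ± 83.5 (SD, n = 4) in Il12rb2-deleted libraries, a log2 difference of 3.57 (SE 0.86), and Tgfa differed by 1.44 (SE 0.32). Other lists passed camera but not with an estimated correlation, whose adjusted p is the last value in each bracket. Basal adhesion genes (20 of 22 higher, median 0.46, camera adjusted p = 5.12e-09, and 0.147), glycolysis and hypoxia genes (20 of 22, 0.47, 4.49e-11, 0.147), NF-kB genes (13 of 18, 0.53, 1.11e-05, 0.113) and matrix genes (18 of 24, 0.38, 2.27e-05, 0.196) were higher too. So were unfolded protein response genes (15 of 18, 0.36, 1.1e-05, 0.147) and immediate-early genes (17 of 20, 0.38, 8.84e-07, 0.297), while the 12 mitochondrial transcripts were all lower (median -0.64, 2.11e-05, 0.339). Glycolysis and immediate-early genes had 1 member each adjusted over the list alone. Several of these medians moved with 1 library left out. Without Il12rb2-deleted replicate 4 the median was 0.74 for wound genes, 0.34 for alarmins and 0.23 for matrix genes. Without floxed control replicate 1 it was 0.23 for matrix and 0.18 for immediate-early genes, and without floxed control replicate 2 it was 0.11 for the unfolded protein response.

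The type I interferon list was lower in Il12rb2-deleted untreated cells in all 30 members (median -1.03, camera adjusted p = 2.48e-08, and adjusted p = 0.339 with an estimated correlation), but without floxed control untreated replicate 1 its median was 0.58 (adjusted p = 0.871). It was -3.03 without Il12rb2-deleted replicate 2 and -0.66 without replicate 3. The antigen presentation list (median -0.28, -0.57 to -0.0345 with a library left out, adjusted p = 0.000471) rested on the same library (adjusted p = 0.297 without it). A further 8 lists passed camera but not with some library left out. Of those higher in Il12rb2-deleted cells, cell cycle (median 0.20, 0.0555 to 0.50 with a library left out, adjusted p = 0.000243) did not pass without floxed control replicate 2 (0.282) or Il12rb2-deleted replicate 4 (0.144). Cholesterol biosynthesis (0.22, range 0.22 to 0.45, adjusted p = 0.000148; 1 member adjusted over the list alone) did not pass without floxed control replicate 2 (0.0834) or Il12rb2-deleted replicate 3 (0.159). Interleukin-12 and -23 signalling (0.22, range -0.0222 to 0.42, adjusted p = 0.0257) did not pass without floxed control replicate 1 (0.367) or Il12rb2-deleted replicate 1 (0.182) or 2 (0.0614), nor suprabasal differentiation (0.28, range 0.11 to 0.45, adjusted p = 0.0241) without Il12rb2-deleted replicate 3 (0.121) or 4 (0.208). Of the marker lists that were lower, melanocytes and Merkel cells (-0.78, range -1.26 to -0.47, adjusted p = 0.00367) did not pass without floxed control replicate 2 (0.0507), and endothelial and mural cells (-0.36, range -1.34 to 0.0424, adjusted p = 0.00631) without floxed control replicate 1 (0.0598) or 3 (0.133) or Il12rb2-deleted replicate 3 (0.0843) or 4 (0.112). Sebaceous cells (-0.36, range -0.76 to 0.15, adjusted p = 0.0237) did not pass without floxed control replicate 1 (0.508) or Il12rb2-deleted replicate 1 (0.955) or 4 (0.18), nor hair follicle (-0.53, range -0.98 to -0.21, adjusted p = 0.0241) without floxed control replicate 1 (0.38) or Il12rb2-deleted replicate 1 (0.126) or 4 (0.208). Of these 9 lists the antigen presentation list had an adjusted p of 0.368, suprabasal differentiation 0.431, sebaceous cells 0.526, interleukin-12 and -23 signalling 0.316 and the other 5 lists 0.339 with an estimated correlation. The type 3 list had a median of -0.61 (range -0.79 to 0.69) and a mean of -0.12 with camera's direction up. Barrier lipid, NRF2, clock, type 3, fibroblast, Langerhans cell, T cell and neutrophil lists did not pass (adjusted p = 0.111, 0.109, 0.249, 0.553, 0.36, 0.427, 0.409 and 0.629). Of these, barrier lipids passed without floxed control replicate 3 (0.0365) and NRF2 without floxed control replicate 1 (0.0447) or 3 (0.0304). No list passed fry.

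After Aldara, Il12rb2-deleted keratinocytes had lower fibroblast and melanocyte or Merkel cell transcripts and higher type 3 and wound transcripts than floxed control cells as lists by camera, again with no gene called singly. None of these 4 lists passed with an estimated correlation (adjusted p = 0.306, 0.306, 0.306 and 0.683). The type 3 call was lost without Il12rb2-deleted replicate 1 (adjusted p = 0.0534), and the wound call without floxed control replicate 1 (0.398) or Il12rb2-deleted replicate 2 (0.054) or 3 (0.167). Ccdc80 was at 4.88 ± 0.720 CPM (SD, n = 3) in floxed control and 0.342 ± 0.271 (SD, n = 3) in Il12rb2-deleted libraries, a log2 difference of -3.89 (SE 0.69, edgeR adjusted p = 0.487). Hspb1, a small heat shock protein gene (chromosome 5, 135887919 to 135889563, plus strand), was at 171 ± 2.96 CPM (SD, n = 3) and 355 ± 4.69 (SD, n = 3), a log2 difference of 1.06 (SE 0.19, adjusted p = 0.487). Slc24a3 (-2.19), Slc2a6 (-4.00) and Igfbp5 (-5.92, and -2.42 without floxed control replicate 3) followed at an adjusted p of 0.982, and Krt14 and Krt5 differed by 0.13 and 0.21 (adjusted p = 0.988 and 0.986). EdgeR called 0 genes. An unadjusted p under 0.05 was reached by 690, a smaller share of the 16051 tested than the 0.05 that chance alone gives on average. DESeq2 called 30 (6 higher, 24 lower), limma voom 2 (Hspb1 and Pctp) and edgeR with no filter 1 (Ccdc80). On simulated data for this comparison 14 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered.

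Of 18 fibroblast markers 16 were lower in Il12rb2-deleted Aldara libraries (median -1.27, camera adjusted p = 8.67e-09, and adjusted p = 0.306 with an estimated correlation), 2 of them adjusted over the list alone, with Lum at -2.99 (SE 0.82; -1.89 without floxed control Aldara replicate 2) and Fstl1 at -1.40 (SE 0.37). Without Il12rb2-deleted Aldara replicate 1 the median was -0.80. Of 14 melanocyte and Merkel cell markers 13 were lower (median -1.57, and -2.37 without Il12rb2-deleted Aldara replicate 2, camera adjusted p = 4.24e-05, and adjusted p = 0.306 with an estimated correlation). Krt8, a keratin of Merkel cells, was at 75.1 ± 115 CPM (SD, n = 3) and 4.02 ± 2.84 (SD, n = 3). Type 3 genes were higher in 16 of 19 (median 0.93, camera adjusted p = 0.00319, and adjusted p = 0.306 with an estimated correlation), a call lost without Il12rb2-deleted Aldara replicate 1 (median 0.58, adjusted p = 0.0534). S100a8 was at 19.7 ± 8.24 CPM (SD, n = 3) in floxed control and 97.9 ± 47.2 (SD, n = 3) in Il12rb2-deleted libraries, a log2 difference of 2.31 (SE 1.01), and Cxcl1 at 70.3 ± 14.9 and 163 ± 91.2 CPM (SD, n = 3 each). The wound list (14 of 20 higher, median 0.91, range 0.51 to 1.44, camera adjusted p = 0.00355, and adjusted p = 0.683 with an estimated correlation) lost its call without floxed control Aldara replicate 1 (adjusted p = 0.398) or Il12rb2-deleted Aldara replicate 2 (0.054) or 3 (0.167). The antigen presentation list (17 of 25 higher, median 0.16, range -0.0190 to 0.37, camera adjusted p = 0.0262, and adjusted p = 0.935 with an estimated correlation) lost it without floxed control Aldara replicate 1 (adjusted p = 0.561) or Il12rb2-deleted Aldara replicate 2 (0.298) or 3 (0.489). Mitochondrial transcripts (10 of 12 lower, median -0.85, range -1.23 to -0.35, camera adjusted p = 0.000173, and adjusted p = 0.683 with an estimated correlation) lost it without floxed control Aldara replicate 2 (0.0809) or Il12rb2-deleted Aldara replicate 3 (0.167). Hair follicle markers (15 of 20 lower, median -0.59, range -0.92 to -0.12, camera adjusted p = 0.0262, and adjusted p = 0.683 with an estimated correlation) lost it without floxed control Aldara replicate 1 (0.126) or 3 (0.189) or Il12rb2-deleted Aldara replicate 2 (0.0738) or 3 (0.167). No member of these 5 lists passed adjusted over the list alone except 2 mitochondrial transcripts. The other 20 lists did not pass camera, and the type I interferon list had a median of -0.10 (adjusted p = 0.867). Of these 20, 8 passed without some library, among them immediate-early genes without any 1 of 6 libraries (down to an adjusted p of 9.75e-12 without floxed control Aldara replicate 3) and sebaceous markers without floxed control Aldara replicate 3 (0.00073).

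**Figure D4:**
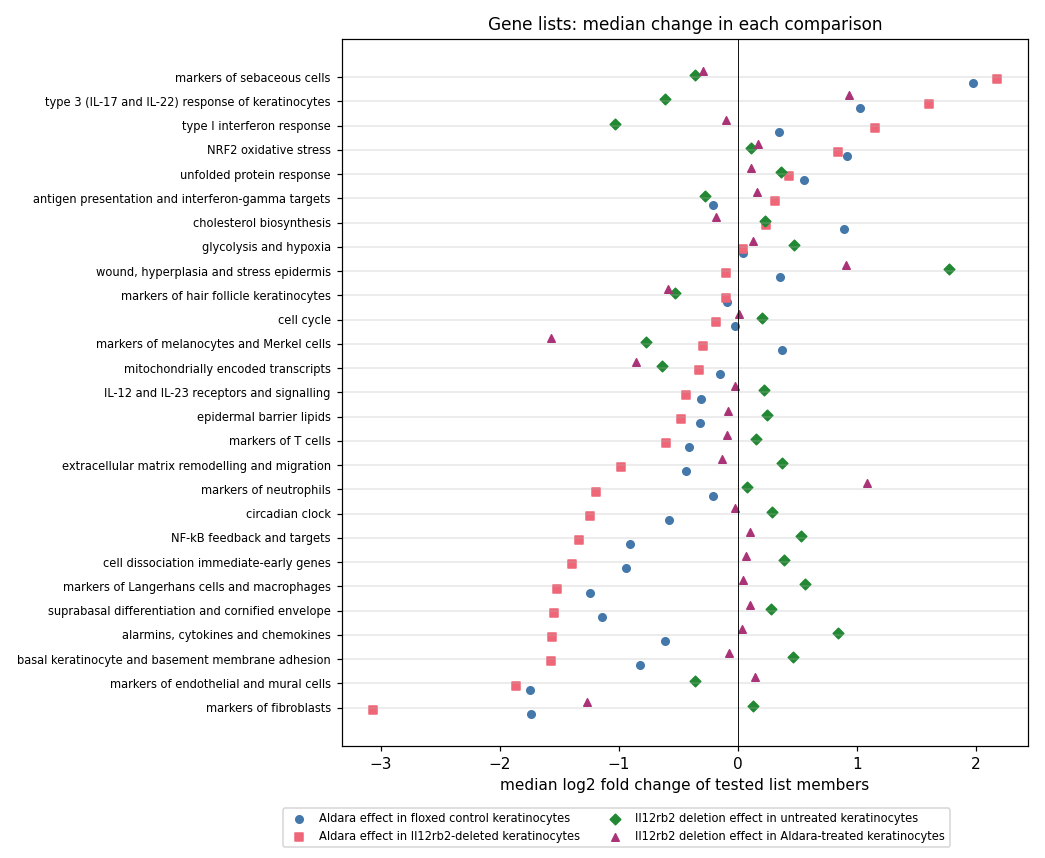
Median log2 fold change of the tested members of 27 gene lists (rows) in the 4 comparisons of 2 groups, 1 symbol per comparison, with no error bars because members of a list are not replicates. Sebaceous markers lie at 1.98 and 2.18 for Aldara in the 2 genotypes, and fibroblast markers at -1.74 and -3.07.

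The interaction asked whether the Aldara effect differed between genotypes. By camera the Aldara change of fibroblast and basal adhesion genes as lists was more negative in Il12rb2-deleted than in floxed control cells. That of the list of antigen presentation and interferon-gamma target genes was more positive. None of the 3 passed with an estimated correlation (adjusted p = 0.522, 0.522 and 0.538), and no gene was called singly. The genes with the smallest p were Ccdc80 (-4.54, SE 0.85), Slc2a6 (-4.68, SE 1.15), Tnip3 (-4.16, SE 1.07), Asap1 (-1.54, SE 0.40) and Lipg (-3.58, SE 0.94), each at an edgeR adjusted p of 1. Il12rb2 differed by -0.76 (SE 1.06), from -1.46 without Il12rb2-deleted Aldara replicate 3 to 0.0693 without floxed control Aldara replicate 2, so its sign was not fixed. Krt14 differed by -0.70 (SE 0.49) and Krt5 by -0.43 (SE 0.43). EdgeR called 0 genes. An unadjusted p under 0.05 was reached by 539, a smaller share of the 16051 tested than the 0.05 that chance alone gives on average. Limma voom called 0 and DESeq2 called 3 (Ccdc80, and Grk3 and Syne3, which were chosen after their values were seen). Without floxed control untreated replicate 3, edgeR called 1, Ccdc80. On simulated data for the interaction 0 of 100 genes changed 2-fold and 13 of 100 changed 4-fold were recovered, so differences of these sizes between the Aldara effects were mostly not detectable here.

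Of the lists, 10 passed camera for the interaction and none with an estimated correlation, where the smallest adjusted p was 0.522. Fibroblast markers were lower in 17 of 18 (median -1.28, camera adjusted p = 9.63e-08), basal adhesion genes in 20 of 22 (-0.60, 1.66e-05) and matrix genes in 19 of 24 (-0.57, 0.00124), and antigen presentation genes were higher in 21 of 25 (0.56, 1.73e-05). These 4 kept the call with each library left out, and their adjusted p was 0.522, 0.522, 0.522 and 0.538 with an estimated correlation. The matrix median was -0.31 without floxed control Aldara replicate 3 and -0.24 without Il12rb2-deleted Aldara replicate 1. The antigen presentation median was 0.16 without floxed control untreated replicate 1, 0.91 without Il12rb2-deleted untreated replicate 2, 0.86 without floxed control Aldara replicate 3 and 0.37 without Il12rb2-deleted Aldara replicate 3. Cxcl9 was at 18.7 ± 6.05 (SD, n = 3) and 9.26 ± 9.35 CPM (SD, n = 3) before and after Aldara in floxed control cells. In Il12rb2-deleted cells it was at 7.95 ± 8.24 (SD, n = 4) and 36.5 ± 16.5 CPM (SD, n = 3), an interaction of 3.27 (SE 1.04). The other 6 did not pass without some library. Cholesterol biosynthesis (median -0.55, adjusted p = 0.000324, with Sqle adjusted over the list alone) depended on Il12rb2-deleted untreated replicate 3 (0.0506 without it), and glycolysis and hypoxia (-0.39, range -0.60 to -0.21, adjusted p = 0.000444) on floxed control untreated replicate 2 (0.11). Alarmins, cytokines and chemokines (-0.55, range -0.78 to -0.19, adjusted p = 0.00306) depended on floxed control Aldara replicate 3 (0.0636) and type I interferon (0.81, range -0.78 to 2.66, adjusted p = 0.000444) on floxed control untreated replicate 1 (0.685). Cell cycle (-0.30, range -0.48 to -0.10, adjusted p = 0.0135) did not pass without floxed control untreated replicate 2 (0.414), Il12rb2-deleted untreated replicate 4 (0.445), floxed control Aldara replicate 1 (0.0646) or 2 (0.0509) or Il12rb2-deleted Aldara replicate 2 (0.129). Type 3 genes (0.93, range 0.28 to 1.53, adjusted p = 0.0481) passed only in the fit of all libraries and without Il12rb2-deleted untreated replicate 2 or 4, with an adjusted p of 0.0574 to 0.556 without each of the other 11. Of the 17 lists that did not pass, 9 passed without some library, down to an adjusted p of 0.000338 for immediate-early genes without floxed control Aldara replicate 1.

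**Figure D5:**
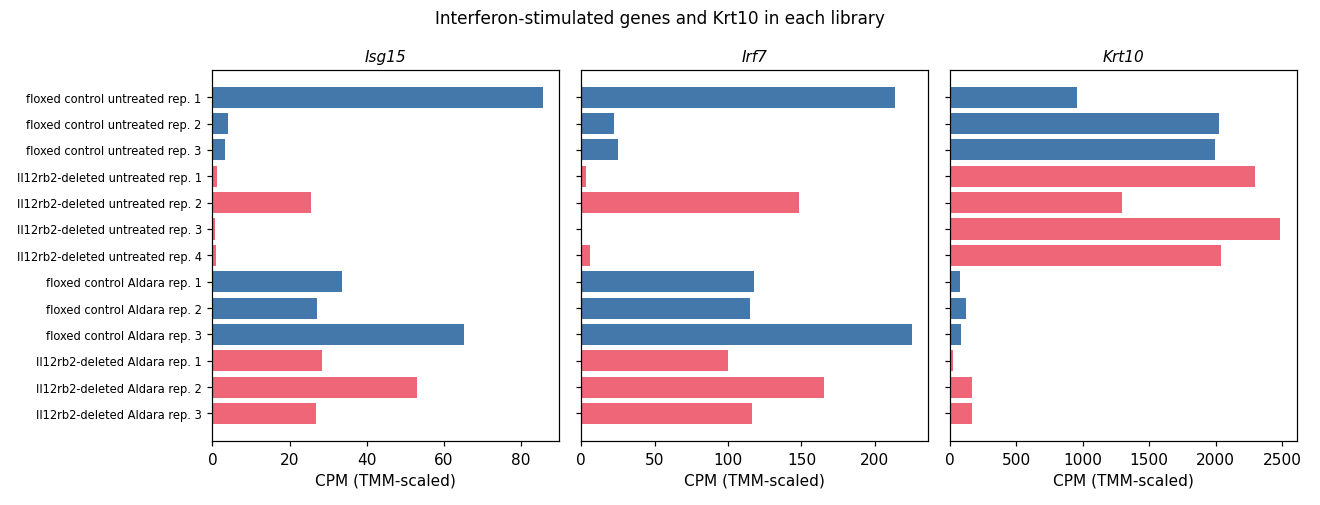
CPM of the interferon-stimulated genes Isg15 and Irf7 and of Krt10 as 1 bar per library, with no error because each bar is 1 library. Among untreated libraries Isg15 is 85.7 CPM in floxed control replicate 1 and 25.5 CPM in Il12rb2-deleted replicate 2, and 3.94 CPM or less in the other 5. Krt10 is lower in the first (955.9 CPM) and the second (1298 CPM) than in the other 5 (1999 CPM or more), and is 169 CPM or less in the Aldara libraries.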

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

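Splits of the libraries were planned, the comparison of lists between genotypes rests on the planned interaction, and the 3 tests on fibroblast markers were chosen after the result was seen.

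The Aldara effect differed between genotypes in 10 gene lists by the interaction in camera. The adjusted p was 9.63e-08 for fibroblast markers, 1.66e-05 for basal adhesion, 1.73e-05 for antigen presentation, 0.000324 for cholesterol biosynthesis, 0.000444 each for type I interferon and for glycolysis and hypoxia, 0.00124 for matrix genes, 0.00306 for alarmins and cytokines, 0.0135 for cell cycle and 0.0481 for type 3 genes. None passed with an estimated correlation, where the smallest adjusted p was 0.522. With 1 library left out, 6 of the 10 lost the call: type I interferon without floxed control untreated replicate 1 (adjusted p = 0.685, median -0.78), type 3 genes without any 1 of 11 libraries, cell cycle without any 1 of 5, and cholesterol biosynthesis (up to 0.0506), glycolysis and hypoxia (0.11) and alarmins and cytokines (0.0636) without 1 library each.

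Fibroblast markers were lower in Il12rb2-deleted than in floxed control libraries after Aldara (median -1.27, with an adjusted p of 0.306 with an estimated correlation). A single library as the whole cause of the camera call is argued against, since the highest camera adjusted p with each of the 6 libraries left out in turn was 1.97e-05 and the median stayed at -0.80 or lower. Fewer dermal cells of every kind cannot be told apart: the endothelial and mural list lay above the fibroblast list by 1.41 (permutation p over list members = 0.0128), but without Il12rb2-deleted replicate 1 their medians were -0.45 and -0.80. Fewer fibroblasts alone cannot be told apart from a lower output per cell, since the 5 most abundant markers (Col3a1, Gsn, Dcn, Sparc and Col1a1; median -0.97) are members of the list found lower and so do not test it. An effect of the genotype on these transcripts stays open and was not tested.

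In the group of 4 Il12rb2-deleted untreated libraries, 1 library lay far from the other 3 in log2 CPM for 15 of 315 named genes by Dixon's test at 0.05. Chance alone gives this in about 1 of 20 groups, so 15 of 315 is no excess over chance. The values are the gap as a share of the group's range. At a value of 1 the other 3 libraries had no spread at the digits given. Among those reported here, replicate 2 stood apart for Gclm (0.841), Cxcl10 (0.839), Usp18 (0.935), Dsg1a (0.902), C1qc (0.901), Adamts14 (0.833) and Chac1 (0.854). Replicate 1 stood apart for Fabp5 (0.841), Cxcl1 (0.868) and Manf (0.9), replicate 3 for Hmox1 (0.859), and replicate 4 for S100a8 (0.894) and Sdr9c7 (1).

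Other splits of the same libraries bear on the counts of genes called. For the Aldara effect in Il12rb2-deleted cells 1 of 35 splits, the real one, gave as many as 2489 genes. The highest other gave 608, with Il12rb2-deleted untreated replicate 2 placed with the Aldara libraries. This puts the share under 0.05 but does not exclude chance, since 35 splits allow no smaller share. The other contrasts were split too, and no correction was made for that. In floxed control cells the real split gave 1132 and the highest of the other splits 0, but 10 splits are too few for a share under 0.05. For the deletion effect in untreated cells, the real split called 0 genes, so 35 of 35 splits gave as many by construction, which does not test chance. The highest other split called 24, with floxed control replicate 3 and Il12rb2-deleted replicates 3 and 4 apart from the rest. These are the 3 libraries with the lowest share of counts in Gm10800, which points to a structure of the samples. With them as a batch term the real split again called 0. For the deletion effect after Aldara all 10 splits called 0, too few for a share under 0.05. For the interaction the real split called 0 as well, so all 100 of 100 drawn splits gave as many by construction, with up to 11 in another split.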

How the results depend on the processing

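The alternatives that use Gm10800 and all tests of the agreement of the deletion effects were chosen after the data were seen. RLE size factors, a minimum count of 50, 1 surrogate variable and fits of only the groups compared left every count of called genes within 1.5 times. No call of an Aldara effect changed sign with a library left out. DESeq2 called 2160 genes for Aldara in floxed control cells, 18 for the deletion untreated, 30 after Aldara and 3 for the interaction. Limma voom called 2029 and 3900 genes for Aldara in floxed control and Il12rb2-deleted cells and 2 for the deletion after Aldara. Without a filter on low counts 3 and 1 genes were called for the deletion untreated and after Aldara. Without the 3 libraries high in Gm10800, which leaves fewer samples, the Aldara counts were 270 and 1466, of which 265 and 1266 were among the calls above. There the Aldara change of Il12rb2 in floxed control cells was -3.05 (adjusted p = 0.13). With each library left out, counts ran from 215 to 1451 and from 1650 to 2764 for Aldara in the 2 genotypes, and from 0 to 1 for the interaction. The Il12rb2 change in floxed control cells ran from -4.40 to -3.05. The correlation of the Aldara effects ran from 0.357 to 0.539, and was 0.262 with DESeq2, 0.248 without a filter, 0.725 at a minimum count of 50, 0.377 without the 3 libraries and 0.851 over called genes. The correlation of the deletion effects (0.0566) ran from -0.0523 to 0.103. Lists called for the deletion after Aldara ran from 3 to 12. With an estimated correlation 0 lists were called in any of the 5 contrasts, and with fry 0 in the deletion contrasts and the interaction. Fry called 8 of 27 lists for Aldara in floxed control cells and 13 of 27 in Il12rb2-deleted cells. With a library left out, the list median changed side in some results, of which not all are given here. The cause was not tested. For the deletion untreated the median ran from -3.03 to 0.58 for type I interferon and from -0.0222 to 0.42 for interleukin-12 signalling. It ran from -0.76 to 0.15 for sebaceous markers, from -1.34 to 0.0424 for endothelial markers and from -0.79 to 0.69 for type 3 genes, which did not pass camera. For the deletion after Aldara it ran from -0.0190 to 0.37 for antigen presentation and from -0.39 to 0.37 for suprabasal genes, which without Il12rb2-deleted replicate 1 had a median of 0.19 (adjusted p = 0.00345). For the interaction it ran from -0.78 to 2.66 for type I interferon. Whether the replicate numbers pair the libraries was not settled. Of 18 same-numbered pairs 6 had a correlation of deviations over 0.1 (lowest -0.163, highest 0.421), and 6 of 13 libraries correlated best with their own number. The median correlation was -0.000399 over same-numbered pairs and -0.00216 over other pairs. A pairing of some libraries by number is therefore neither shown nor excluded. With the replicate block 831 and 1919 genes were called for Aldara and 0 in the other contrasts. Simulated 2-fold changes were recovered in 8, 14 and 0 of 100 genes in the deletion contrasts and the interaction, and in 5 and 10 in the Aldara contrasts.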

Other observations

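The test for genomic DNA was written before its result was seen, and all other tests here were chosen afterwards.

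The untreated libraries fell apart in their share of counts in Gm10800. Of the 4 comparisons of 2 groups, 0 had ranges of that share without overlap. That test cannot detect a difference in spread. The share ran from 0.000543% to 14.17% in untreated libraries and from 0.0483% to 2.22% in Aldara libraries. High and low untreated libraries were found in both genotypes. Whether the pattern goes with Aldara treatment therefore stays open. The 3 libraries with over 5% also held counts in 1320, 1166 and 1112 of 1524 olfactory and vomeronasal receptor genes. That number was 661 and 141 in floxed control untreated replicates 1 and 3, and 16 and 27 in Il12rb2-deleted untreated replicates 3 and 4. It was 510 to 919 in the Aldara libraries. Genomic DNA in the library may account for this: counts of those receptor genes rose with exonic length, with a Spearman rho across genes of at least 0.568 in each of the 3 libraries (genes are not independent replicates). This was not particular to them, since rho was 0.478 in floxed control untreated replicate 1 and 0.358 to 0.521 in the 6 Aldara libraries, and 0.218, 0.0625 and 0.138 in floxed control untreated replicate 3 and Il12rb2-deleted untreated replicates 3 and 4. Reads that map to several places could also add to Gm10800 and stay open, as their treatment is not given.

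Type I interferon genes were high in 1 untreated library of each genotype, floxed control replicate 1 (Isg15 at 85.7 CPM, Irf7 at 214 CPM) and Il12rb2-deleted replicate 2 (25.5 and 148 CPM). A wrong label on Aldara-treated skin is argued against. Over genes called for Aldara in the other genotype these libraries sat at 0.29 and 0.0907 of the way from the untreated to the Aldara mean. Krt10 was at 955.9 and 1298 CPM, against 169 CPM or less in Aldara libraries. Yet the other untreated libraries sat at -0.123 to 0.051 and held Krt10 at 1999 to 2488 CPM. A partial shift of these libraries toward the Aldara state is not excluded and was not tested. Leukocytes in the sort cannot be told apart: 6 leukocyte genes summed to at least 225.5 CPM in both libraries against a median of 116.4 over untreated libraries. Cd74, which the antigen presentation list also holds, made up 208.9 of that, and without it floxed control replicate 1 lay at 16.6 against a median of 23.0, a comparison added after the first result was seen. The design names no group for this pattern, so no biological explanation was tested.

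The deletion differences before and after Aldara were nearly unrelated across 16051 genes, which are not independent replicates, with Pearson's r of 0.0566, Spearman's rho of 0.0953 and the same sign in 54.9%.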
